A study of Mus musculus with 12 samples.

How the data were processed

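Hypothalamic polyadenylated RNA from 12 libraries was sequenced on an Illumina HiSeq instrument, per the labels' protocols. The deposited file of each library lists a transcript identifier and a raw count, per the file headers. TopHat, HTSeq and the mouse genome build mm9 are named, per the submitters' processing notes, and their versions and settings are not given in the sources used here. Whether the counting used strand is likewise not given. Each deposited file holds only transcripts with a count of at least 1, and a transcript missing from a file was taken as a count of 0. The files listed 48536 transcripts in all, of which 43854 were in every file. No normalization had been applied, since the count totals differ between libraries.

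The identifiers are those of UCSC known genes. Neither the files nor the reference tables used here (GENCODE M21 and RefSeq on GRCm38, another build than mm9) pair them with symbols, and 0 of the 48536 identifiers occurred in them. The 34 gene lists, the test of long genes and the values of Mecp2 and Irak1 that had been planned were therefore not analysed here. In place of about 24 named genes per comparison, 2 transcripts that rose and 2 that fell are named. They are the leading one of each direction in each comparison, by the rule fixed before the data were examined. That rule ranks transcripts by log2 fold change among those with adjusted p under 0.05, an average log2 CPM of at least 1, and 3 mutant libraries all outside the range of the 3 wild type libraries. The leading 12 per direction are summarised by their range. For transcripts called in both comparisons, the 8 with the smallest larger adjusted p stand for each class.

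Whether reads were counted more than once was tested from the values. For neighbouring identifiers with summed counts of at least 200, a chi-square statistic over the 12 libraries was set against its lower tail. Counts that agree more closely than independent counting allows (lower-tail p under 0.001) must share reads. This held for 7570 of 43692 pairs of next neighbours (17.3%) and for 0 of 42693 pairs that lay far apart in the list. Linking such pairs up to 5 steps apart left 35278 groups, and 14223 transcripts (32.6%) sat in groups of at least 2. On simulated pairs the test called 100% of those sharing 95% of reads, 39.25% of those sharing 80% and 0.1% of independent ones, so the grouping is a lower bound. Counts of changed transcripts are thus not counts of genes. Taking the most abundant transcript of each group kept 75.9% to 76.5% of the counts.

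Transcripts were kept by edgeR's filterByExpr (43693 kept, 4843 removed), scaled by TMM factors and fitted with edgeR's quasi-likelihood model (glmQLFit with robust estimation, glmQLFTest). All 12 libraries entered a single fit with a mean per group, so that the 4 groups shared an estimate of the spread. Contrasts gave the knockout against its wild type, the transgenic against its wild type and the difference of both effects. P-values were adjusted by Benjamini-Hochberg within a contrast, with a threshold of 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. CPM values use TMM-scaled library sizes, except in the filter of at least 1 CPM and the search for transcripts of single libraries, which scale to the total count, and means ± SD are over 3 libraries.

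The fit was tested on simulated data drawn from the real means, dispersions and library sizes, with 43474 transcripts fitted. Only transcripts above 1 CPM were changed, and the simulated spread was the fitted negative binomial dispersion without the additional quasi-likelihood spread. The recovered shares therefore do not hold for rarer or noisier transcripts. Far fewer transcripts were changed than were called in the real data, which makes the adjusted threshold stricter in the simulation. Neither the shares nor the false calls are thus bounds for the real fit. In the knockout comparison 70.15% of 1.25-fold, 92.54% of 1.5-fold and 100% of 2-fold changes were recovered, and 7 of 43274 unchanged transcripts were called. In the transgenic comparison the shares were 71.64%, 98.51% and 100%, with 9 unchanged transcripts called. In the simulated difference of effects 316 transcripts were called, and they held 297 of the 400 simulated changes.

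Replicate libraries of a group differed by more than sampling noise (chi-square per degree of freedom 8.04 to 77.32), so none was treated as a duplicate. Among low counts of 1 to 20, 64.02% to 71.74% were even numbers. Counts were therefore not read as independent molecules, and no counting intervals are given.

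The alternatives fixed before the data were examined were DESeq2, median-of-ratios factors, no low-count filter, a filter of at least 1 CPM in 3 libraries and fits of each cohort alone. The others were a block for the replicate number, thinning to the smallest library and leaving out each library. An analysis of 1 transcript per read-sharing group and scaling to the total count alone were added after seeing the data. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.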

Results

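MeCP2 is a nuclear protein that binds methylated DNA. Loss of its gene underlies Rett syndrome, and an extra copy causes a separate neurological disorder. Polyadenylated RNA was sequenced from the hypothalamus of 7-week-old mice in 4 groups of 3 libraries each. MeCP2 knockout mice had their own wild type controls, and mice carrying a MeCP2 transgene had a separate set of wild type controls, each matched for age and genetic background. The 12 count tables held totals of 386027712 to 533071159 per library, with a mean of 485752486 ± 15275056 (SD, n = 3) in the knockout and 480888999 ± 78493214 (SD, n = 3) in its wild type. Totals averaged 439181229 ± 49466915 (SD, n = 3) in the transgenic group and 491700741 ± 26867051 (SD, n = 3) in its wild type. These totals are not numbers of reads, since some overlapping transcripts shared reads.

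Counts were keyed by UCSC known-gene transcript identifiers, which the files do not pair with gene names. The changes are therefore described by number, direction, size and abundance class, and 4 transcripts stand as examples under their identifiers. Mecp2 itself, the targeted gene, was for the same reason not analysed here, so the genotype labels were taken as given. The labels do not say that the libraries of a group came from separate animals. The p-values then measure the spread between these libraries only, which may be technical.

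The first principal component of log2 CPM (counts scaled to TMM-adjusted library totals) held 46.45% of the variance and ordered the libraries by genotype. The 3 knockout libraries lay between -53.4 and -47.5 on it, the 6 wild type libraries between -5.0 and 0.7, and the 3 transgenic libraries between 52.9 and 58.2. The second component held 11.57% and was lowest in transgenic-cohort wild type replicate 3, at -42.52.

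The knockout was compared with its wild type to ask which transcripts depend on MeCP2. Of 43693 transcripts tested, 7834 (17.9%) changed, 4034 of them higher in the knockout and 3800 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Most changes were small. The median change was 0.27 on the log2 scale (1.21-fold) among transcripts that rose and -0.35 (1.28-fold lower) among those that fell. Larger changes were mostly decreases. A change of at least 1.5-fold was seen in 935 transcripts that fell and in 323 that rose, and at least 2-fold in 324 that fell and 50 that rose.

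The largest decrease among transcripts whose knockout and wild type libraries did not overlap, at an average log2 CPM of at least 1, was that of uc009tnu.1. It averaged 99.8 CPM ± 1.75 (SD, n = 3) in the wild type and 9.30 CPM ± 3.29 (SD, n = 3) in the knockout. Its log2 fold change was -3.42 (SE 0.22), a 10.7-fold decrease, with an edgeR adjusted p of 5.96e-06. In the transgenic comparison the same transcript differed by 0.09 (SE 0.20, edgeR adjusted p = 0.785), from 98.2 CPM ± 1.40 (SD, n = 3) to 104.4 CPM ± 3.46 (SD, n = 3). That SE rests on a spread shared by the 4 groups, and the knockout libraries scattered most relative to their mean. The transgenic libraries (101.1 to 108.0 CPM) all lay above their wild type (97.1 to 99.8 CPM), so a small increase is not excluded. The next decrease in rank, -3.4 (SE 0.21), was that of a neighbouring identifier, which differed by 0.16 (SE 0.19) in the transgenic. Mecp2 could not be located among the identifiers, so these decreases may be of the targeted gene itself. The largest increase by the same rule was that of uc007wot.1, from 8.66 CPM ± 0.737 (SD, n = 3) to 23.0 CPM ± 3.44 (SD, n = 3). Its log2 fold change was 1.41 (SE 0.20, edgeR adjusted p = 0.000882), and in the transgenic it changed by -1.14 (SE 0.21, edgeR adjusted p = 0.003). The 12 leading increases spanned 1.01 to 1.41, and 11 of these transcripts were called lower in the transgenic. The 12 leading decreases spanned -3.42 to -1.22, and 8 of them were called higher in the transgenic. Among all increases called in the knockout 73.5% were called lower in the transgenic, and among all decreases 63.6% were called higher. Both leading lists hold runs of neighbouring identifiers with near-equal values, so their members are not separate genes.

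**Figure D1:**
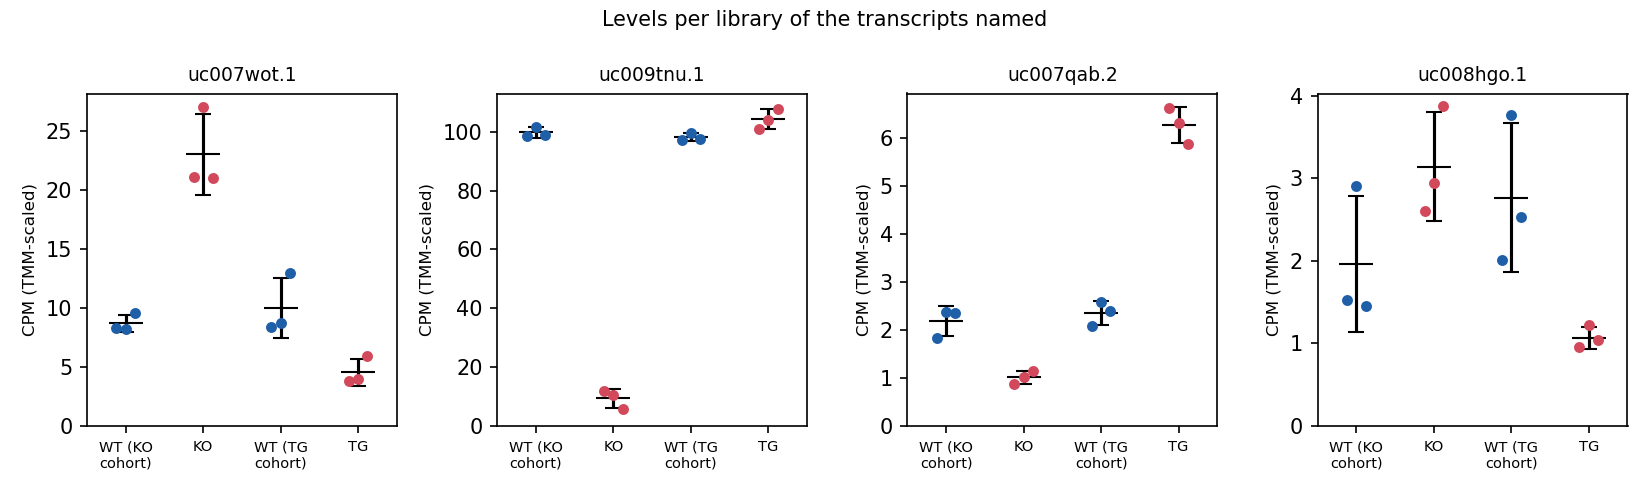
Level of each named transcript in TMM-scaled CPM, on a linear axis starting at 0, for the wild type and mutant libraries of both cohorts (points, 3 libraries per group; bar and whiskers, mean ± SD). The knockout libraries of uc009tnu.1 average 9.30 CPM while the other 3 groups average 98.2 to 104.4 CPM, and uc007qab.2 averages 1.01 CPM in the knockout and 6.28 CPM in the transgenic.

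Direction in the knockout followed abundance. Among the 10328 transcripts under 1 CPM (average log2 CPM below 0), 877 fell and 233 rose, and their median change was -0.106. Among the 25920 transcripts at an average log2 CPM of at least 2, 3235 rose and 2047 fell. The second split depended on scaling, the first did not. With scaling to the total count alone, chosen after seeing the data, 2497 of the abundant transcripts rose and 2894 fell, while under 1 CPM 202 rose and 1014 fell. Over all transcripts that scaling put 39.1% of the changed transcripts above the wild type, against 51.5% with TMM factors.

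The transgenic mice were compared with their wild type to ask which transcripts respond to additional MeCP2. Of the 43693 transcripts, 10956 (25.1%) changed, 5105 higher and 5851 lower in the transgenic (edgeR, adjusted p under 0.05). The median change was 0.36 (1.28-fold) among those that rose and -0.25 (1.19-fold lower) among those that fell. Here the larger changes were mostly increases, with 1331 transcripts at least 1.5-fold higher and 456 at least 1.5-fold lower. At least a 2-fold change was found for 544 that rose and 61 that fell. These counts were likewise not split by abundance, and transcripts under 1 CPM, which mostly rose when called, may hold much of the skew. At an average log2 CPM of at least 1 and without overlap of libraries, the 12 leading changes were similar in size in both directions. The increases spanned 1.09 to 1.42 and the decreases -1.38 to -1.03. Without transgenic replicate 1 the count of changed transcripts was 7016.

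By the same rule as for the knockout, uc007qab.2 led the increases, from 2.35 CPM ± 0.246 (SD, n = 3) in the wild type to 6.28 CPM ± 0.369 (SD, n = 3) in the transgenic. Its log2 fold change was 1.42 (SE 0.11, edgeR adjusted p = 3.6e-06), and in the knockout it fell by 1.12 (SE 0.12, edgeR adjusted p = 2.37e-05). The decreases were led by uc008hgo.1, from 2.77 CPM ± 0.903 (SD, n = 3) to 1.07 CPM ± 0.134 (SD, n = 3), a log2 fold change of -1.38 (SE 0.31, edgeR adjusted p = 0.00909). Its change in the knockout, 0.68 (SE 0.30), did not pass the test (edgeR adjusted p = 0.161). The 12 leading increases spanned 1.09 to 1.42, and 10 of them were called lower in the knockout. The 12 leading decreases spanned -1.38 to -1.03, and 11 of them were called higher in the knockout. Among all increases called in the transgenic 47.3% were called lower in the knockout, and among all decreases 50.6% were called higher. These lists too hold runs of neighbouring identifiers with near-equal values.

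Abundance also separated the transgenic changes, in the reverse sense. Under 1 CPM, 1538 transcripts rose and 358 fell, with a median change of 0.175. At an average log2 CPM of at least 2, 2528 rose and 4742 fell. With total-count scaling the low class held 1689 increases and 300 decreases, and the abundant class 3532 increases and 3611 decreases. That scaling put 59.1% of all changed transcripts above the wild type, against 46.6% with TMM factors.

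**Figure D2:**
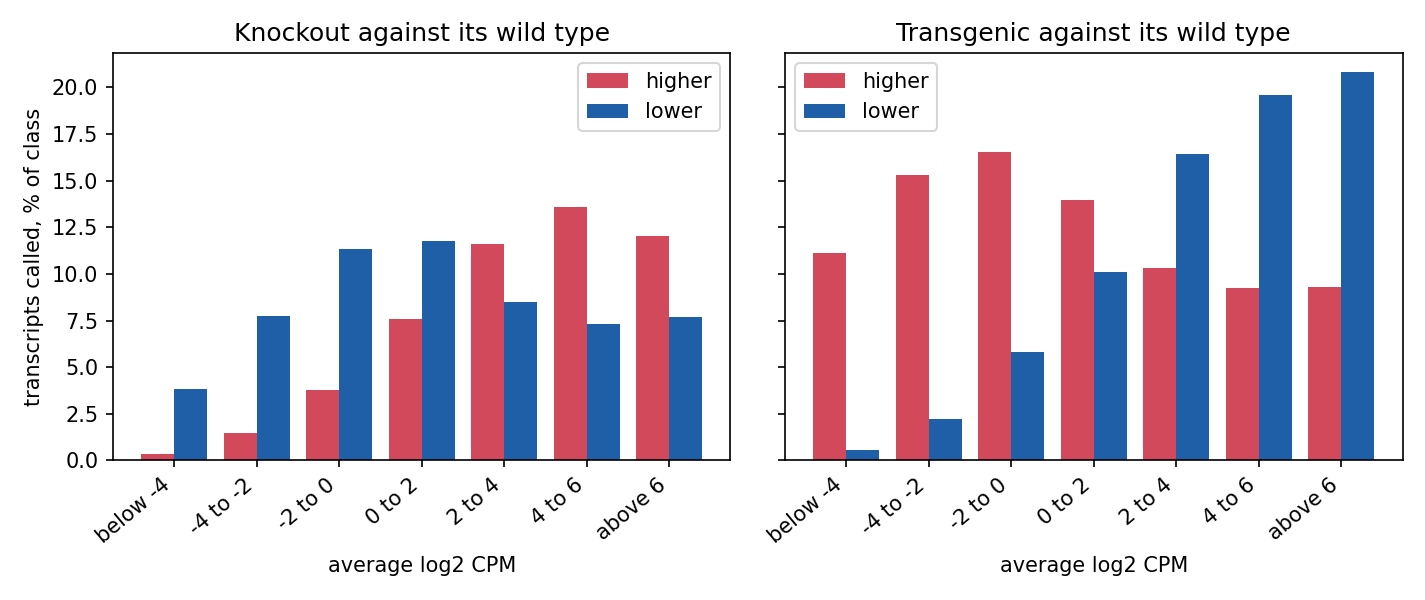
Share of the transcripts in each class of average log2 CPM (x axis) that were called higher or lower than the matched wild type (y axis, percent of the class; edgeR, adjusted p under 0.05), for the knockout on the left and the transgenic on the right. In the lowest class, 92 transcripts fell and 8 rose in the knockout, while 13 fell and 266 rose in the transgenic.

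The design sets loss against gain of one protein, so the directions of both comparisons were set side by side. No control library was shared between them. Of 5427 transcripts that changed in both, 5379 (99.12%) moved in opposite directions and 48 in the same direction. There were 2963 transcripts higher in the knockout and lower in the transgenic, where independent lists of these lengths would share 540.2. Another 2416 were lower in the knockout and higher in the transgenic, where independent lists would share 444. With total-count scaling these classes held 2296 and 3182 transcripts, so which was larger depended on scaling. In each of the classes higher in both and lower in both there were 24, where independent lists would share 471.3 and 508.9. Fisher's exact test of direction among the transcripts called in both gave a p below the smallest number the software can hold. Transcripts that share reads are not independent, so this p is only descriptive.

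Opposite changes were of similar size. The median ratio of the transgenic change to the knockout change, in absolute log2 units, was 1.03 over the 5379 transcripts. These had to pass the same threshold in both comparisons, which favours a ratio near 1. Across all transcripts the fold changes correlated at Spearman's rho -0.59 and Pearson's r -0.52. Across the 25920 transcripts with an average log2 CPM of at least 2 these were -0.70 and -0.75. These are correlations across transcripts, which are not independent replicates. Transcripts that passed in a single comparison leaned the same way. Of 2407 called in the knockout only, 2043 (84.9%) had the opposite sign in the transgenic, and so did 4903 of 5529 (88.7%) called in the transgenic only.

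**Figure D3:**
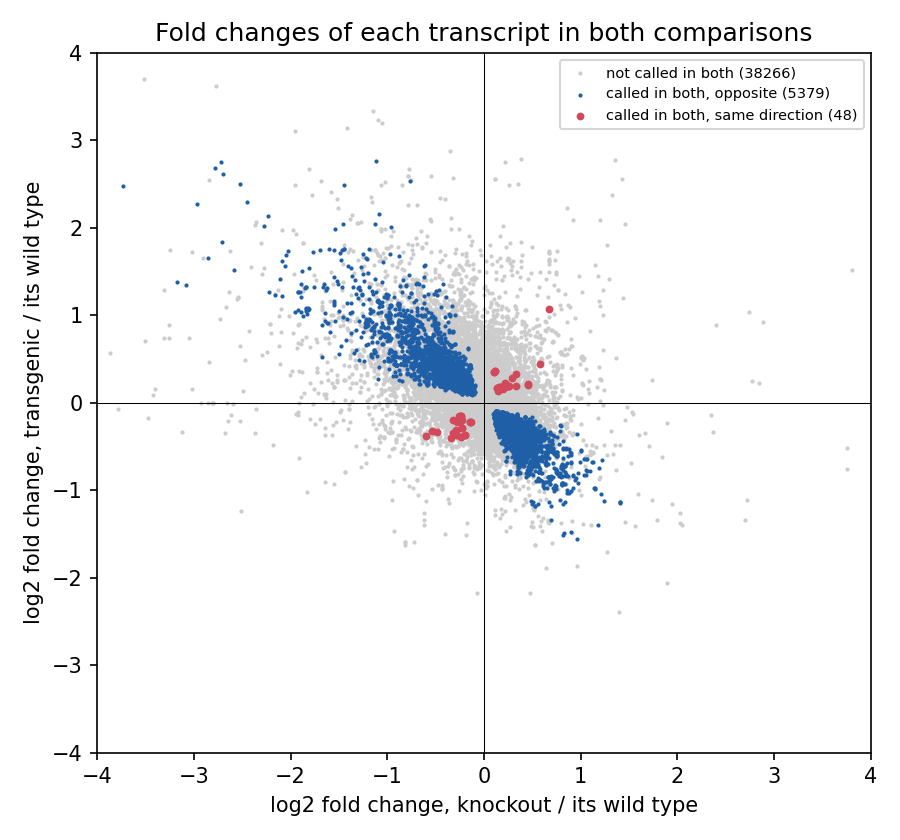
Log2 fold change of each transcript in the knockout against its wild type (x axis) and in the transgenic against its wild type (y axis); colours mark transcripts called in both comparisons, and 16 transcripts lie outside the axes. The 5379 transcripts called in opposite directions fill the upper left and lower right quadrants, and 48 called in the same direction lie in the others.

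Among the 8 transcripts with the smallest larger adjusted p of each class, those higher in the knockout and lower in the transgenic changed by 0.72 to 1.12 and by -1.0 to -0.67. Those lower in the knockout and higher in the transgenic changed by -1.66 to -0.74 and by 0.71 to 1.63. The largest edgeR adjusted p in these classes was 2.61e-06. In the class higher in both, the 8 leading transcripts changed by 0.22 to 0.68 in the knockout and by 0.19 to 1.07 in the transgenic, with edgeR adjusted p up to 0.02. In the class lower in both, the 8 leading changes were -0.49 to -0.19 and -0.37 to -0.2, with edgeR adjusted p up to 0.0212.

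The difference between the knockout effect and the transgenic effect was also tested for each transcript. It passed for 14896 transcripts (34.1%), of which 7617 had the more positive change in the knockout and 7279 in the transgenic (edgeR, adjusted p under 0.05). With total-count scaling these were 5753 and 9582. All 5379 transcripts with opposite calls were among them, as were 6 of the 48 with the same direction. Opposite effects add up in this difference, so the passing of the 5379 follows largely from their calls. The test also passed for 2831 transcripts called in neither single comparison. The 8 strongest differences were 1.29 to 2.53 log2 units in size, with edgeR adjusted p up to 3.93e-09. In 3 of them the knockout rose and the transgenic fell, and in 5 the reverse.

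Levels were also ordered over all 12 libraries. In 3148 transcripts every knockout library lay above all 6 wild type libraries, and these lay above every transgenic library. In 2682 transcripts the order was the reverse. Chance gives either order to a share of 5.41e-05, or 2.4 of the 43693 transcripts.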

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

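The test of wild type spread was chosen only after the principal components had been seen, with its axis set anew without the libraries measured on it, and total-count scaling only after the first results of each comparison. The knockout effect and the transgenic effect differed for 14896 transcripts by the interaction test, the difference between groups that asks for a closer look. The pattern behind it is that 5379 of 5427 transcripts changed in both comparisons moved in opposite directions. Library depth is argued against, because 5235 opposite calls were made after thinning every library to the smallest total. Scaling by a single factor per library is argued against too, since the lower count under total-count or median-of-ratios scaling was 5384. The scalings differed little, with TMM factors of 0.98 to 1.02, and a bias that varies with abundance was not tested. Variation that wild type libraries also show is argued against as the whole cause. On an axis set from 2 knockout and 2 transgenic libraries, the 6 wild type libraries spanned at most 7.59% of the distance between the left-out knockout and transgenic libraries. A difference in handling between the mutant groups stays open, because the labels give no batch, and a response to MeCP2 dose, which the design names, stays open as a hypothesis.

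Regrouping the libraries tested chance. Of 100 splits of both cohorts, 1, the real one, gave as many opposite calls, and the highest of the others gave 0. For the difference of effects, 1 of 100 splits, again the real one, gave 14896 calls, and the highest of the others gave 5031. No split that broke up both cohorts gave a call of a difference. The 0 opposite calls were fixed in advance, since a regrouped cohort gave 0 calls of its own and an opposite call needs both cohorts. No conclusion is drawn from that share. The share for the difference of effects lies under 0.05, which argues against chance in the grouping of both cohorts at once. Even this share is limited, because mixing mutant and wild type libraries in a group widens its spread and lowers the calls of other splits. It cannot exclude chance in the grouping of 1 cohort alone, which has only 10 splits. Nor does it cover libraries of a group that came from the same animal. Each single comparison has only 10 splits of its 6 libraries, too few for a share under 0.05. Of these, 1 gave 7834 calls in the knockout cohort and 1 gave 10956 in the transgenic cohort, the real ones, and the highest other split gave 0 in either cohort. The rank correlation of fold changes is a weaker guide, since other splits reached from -0.50 to 0.46 against the real -0.59.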

How the results depend on the processing

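All 4 counts that answer a comparison stayed within 1.5 times of their value in every alternative run, except for the transgenic comparison without transgenic replicate 1. Leaving out each library in turn gave 5857 to 9162 changed transcripts in the knockout, 7016 to 11605 in the transgenic, 12575 to 14890 for the difference of effects and 4236 to 5590 for opposite calls. The other alternatives gave 5950 to 9262, 8399 to 12356, 11567 to 16031 and 4051 to 6304. Opposite calls made up 98.79% to 99.35% of transcripts called in both comparisons in all of these settings. With 1 transcript per read-sharing group, 5950 changed in the knockout, 8399 in the transgenic and 4051 in opposite directions. Total-count scaling, the other alternative added after seeing the data, moved the median of all transcripts to -0.031 in the knockout and 0.033 in the transgenic and turned the balance of directions as given with each comparison. All 4 named transcripts kept their direction and an adjusted p under 0.05 wherever they were tested. The rank correlation ranged from -0.68, with at least 1 CPM in 3 libraries, to -0.496, without knockout replicate 3. With a replicate block, 6026 transcripts changed in the knockout, 8631 in the transgenic, 12626 in the difference and 4132 in opposite directions. Of the calls made without the block, 75.2% in the knockout and 77.2% in the transgenic were also made with it. Libraries with the same number showed no pairing in the knockout cohort and at most a weak one in the transgenic cohort. Their deviations from the group means correlated at -0.17 to 0.02 in the knockout cohort and 0.03 to 0.10 in the transgenic cohort. In the transgenic cohort each mutant library correlated best with its own number, in the knockout cohort none did. Knockout replicates 1, 2 and 3 correlated best with wild type replicates 3, 1 and 2, at 0.19, 0.14 and 0.31. The replicate block therefore does not test a pairing under other numbers. The tests of gene lists, long genes and Mecp2 were not run in any setting, because the identifiers carry no gene names here. Thinning kept 94.1% of the calls in the knockout and 94.3% in the transgenic.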

Other observations

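The tests of a read background, of identifier prefixes and of signs, and the searches for transcripts of single groups or libraries, were chosen after the results were seen. Transgenic libraries held more transcripts than their wild type, although their mean total was lower. After thinning to the smallest library, 46424 ± 108 (SD, n = 3) transcripts had a count in the transgenic and 45809 ± 131 (SD, n = 3) in its wild type. The knockout had 45623 ± 133 (SD, n = 3) and its wild type 45910 ± 86 (SD, n = 3). The ranges did not overlap in either cohort, which gives 0.1 in a two-sided exact permutation test, the smallest p that 3 against 3 libraries allow. In the transgenic libraries, 9 transcripts had counts of at least 10 in all 3 libraries and at most 2 in each of the other 9 libraries. Their counts ran from 10 to 230. No transcript met that rule for the knockout or for either wild type group, and none was missing from a single group by the converse rule. Of the 9, 4 share an identifier prefix and so lie close together in the list of identifiers. Several had the same counts in every library, and the 9 held only 6 distinct count patterns.

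The median change of transcripts under 1 CPM was below 0 in the knockout (-0.106) and above 0 in the transgenic (0.175), although most of these transcripts passed neither test. Library depth is argued against as the cause, since the transgenic median was 0.171 before and 0.173 after thinning, over the transcripts tested in both. An even background of reads, from genomic DNA or unspliced RNA, cannot be told apart from a change in transcription. In the least abundant class the transgenic exceeded its wild type by a median of 0.00869 CPM, and transcript lengths and intron reads, which would decide it, were not used here. A change in weakly expressed transcripts with MeCP2 dose may thus be followed up as a hypothesis.

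Between the wild types of both cohorts, 87 of 43693 transcripts differed (edgeR, adjusted p under 0.05) and 6271 had an unadjusted p under 0.05. Of the 87, 51 were higher in the knockout cohort and 36 lower. DESeq2 called 924, and the count was 55 without knockout-cohort wild type replicate 3, the lowest of all fits that left out a library. The fit with a replicate block gave 17. There the wild types were compared at the level of replicate 1 only, so 17 is not comparable with the other counts. Of the 87, 43 (49.4%) carry either of 2 neighbouring identifier prefixes that 2.5% of tested transcripts carry. Counted by read-sharing groups this was 31 of 66 (47.0%). The prefixes were picked from these calls, so no test of their share is given. In 73 of the 87 the knockout and transgenic libraries differed with the same sign as their wild types. A genomic difference carried by each mouse line and a batch shared by each cohort would both give this, and they cannot be told apart, as the labels give no batch.

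Single libraries also stood apart. In knockout-cohort wild type replicate 3, 1 transcript reached 89.48 CPM, where the next highest library had 5.09 CPM. In knockout-cohort wild type replicate 1, 4 transcripts with at least 1 CPM there were at least 8-fold above every other library. No other library held such a transcript, and transcripts below 1 CPM in every library were not searched.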
